A study of Mus musculus with 4 samples.

How the data were processed

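Mature miRNAs were measured on 4 one-colour Agilent mouse miRNA arrays, 1 for each of 4 groups of mouse embryonic stem cell (ESC)-derived neural stem and progenitor cells. The groups crossed passage (primary neurospheres, passage 0, 6 days after the embryoid body stage, and secondary neurospheres, passage 1, 12 days after it) with the sample title (control or NFIA OE, for NFIA overexpression). NFIA-overexpressing and control cells were grown together in the same spheres and separated by fluorescence-activated sorting, per the labels and the series description. Small-RNA-containing total RNA was labelled with Cy3 using version 2 of the miRNA Complete Labeling and Hybridization Kit, per the labels' protocols.

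The labels contradict each other on NFIA status. In both passages the array titled control carries a source name that calls its cells the NFIA OE line, and the array titled NFIA OE a source name that calls them WT. Groups follow the titles, and the text writes "titled control" and "titled NFIA OE" throughout. If the source names are right, every signed title difference turns its sign. NFIA is not a miRNA, so the arrays cannot check either label. The comparison of passages does not depend on this.

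The deposited scanner files hold spot intensity on a linear scale, extracted with Feature Extraction 10.5.1.1, per the file headers. The processed intensity of a spot in them is spatially detrended and background-subtracted and is not scaled between arrays, per the file headers. The authors' deposited table of processed values holds 1 linear intensity per miRNA. Its values equalled the scanner's total gene signal divided by 1 constant per array (20.3, 34.1, 33.7 and 31.0 for the primary control-titled, primary NFIA OE-titled, secondary control-titled and secondary NFIA OE-titled arrays), with no log and no centring over genes. Its column medians were 0.882, 0.830, 0.700 and 0.816 in the same order. Why those constants were chosen is not given in the sources used here.

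Each array had 13000 spots outside the controls, for 1857 probes of 611 mouse and 39 viral miRNAs. Spots with an outlier flag were left out, no spot was saturated (0 on each array), and the processed intensities of the remaining spots were averaged per probe. A probe counted as detected on an array when at least 50% of its spots were well above background, and a miRNA when at least 1 of its probes was detected. Each array was divided by its own 75th percentile over the probes detected on all 4 arrays, and values were then put on the log2 scale. A miRNA's value was the mean over its probes detected on every array compared. The standard error over spots was kept as technical error only. The arrays detected 186, 220, 209 and 207 miRNAs in the order given above, and 153 miRNAs were detected on all 4. All arrays came from 1 slide, per the file headers, with position on the slide confounded with title and passage.

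Tests used limma 3.58.1 in R 4.3.3 on the 153 miRNAs. One linear fit over the 4 arrays held title and passage as additive terms, which left 1 residual degree of freedom per miRNA. That residual also holds any interaction of title and passage. The empirical Bayes step estimated an infinite prior, so that every miRNA was judged against 1 pooled residual SD of 0.29 log2, which is also the standard error (SE) of each difference. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05, and such p-values measure only the spread between these arrays. Both arrays of a passage came from 1 mixed culture, so the 2 arrays per passage are not independent cultures. A single pair of arrays has no replicate, so its differences were counted at 2-fold without a test. On simulated arrays with 30 of 153 miRNAs changed, over 20 runs, the fit for title recovered 64.7% of 2-fold and 90.3% of 4-fold changes, with 4.12% false among those called. For passage these were 67.3%, 98.7% and 3.49%. The simulated noise was independent, with the same SD for every miRNA, as the fit assumes, and held no interaction of title and passage. These rates therefore do not cover an interaction or a spread shared among related miRNAs.

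Where a miRNA was detected on only 1 side of a comparison, its fold was given as a lower bound. The bright side's mean was set against the mean, over the dim arrays, of the higher of the probe's own signal and the lowest signal among detected probes. No fold was given where that bound was under 1.

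Named miRNAs were chosen by a rule fixed before the data were examined. For the title and the passage comparison it took the 10 highest and the 10 lowest by the smaller of the differences in the 2 pairs of arrays, with the same sign in both. It added up to 5 one-sided miRNAs per comparison with the largest bound and the 3 miRNAs each way whose title difference changed most between passages. It also added 14 names of prior interest and the member with the largest change each way from each of 20 fixed lists. One of these names, miR-106a, is not used on this array. Other miRNAs named here were chosen after their values were seen. The lists were the miR-17 clusters, the let-7 family, neuronal and neurogenic, reported Nfia-targeting, astrocyte-enriched and oligodendrocyte-enriched miRNAs, the miR-290 and miR-302 clusters, epithelial miRNAs, the Dlk1-Dio3 imprinted cluster, Hox cluster miRNAs, blood cell, mesenchymal (with muscle and endothelial) and endodermal markers, miR-99/100 with miR-125, the miR-181 family, miR-34 with miR-449, the miR-183 cluster, the Sfmbt2 repeats and miR-15 and miR-16 with miR-322 and miR-503. A list's median was placed as a percentile among 10000 random lists of the same size matched on level in 5 bins, as a description of these arrays. Gene neighbours came from a RefSeq gene table of assembly GRCm38.p6. The files name no build, so no coordinates are given.

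Alternatives covered the background correction (normexp with an offset of 50), 5 other ways of scaling (including the authors' processed values), other summaries of probes, other filters, the fit without the other factor, a trend in the prior, and leaving out each array. The offset is added to every spot, which by construction compresses log2 values, most for dim probes. Chosen after seeing the data were a robust prior, correlations without the miR-199 probes and differences taken relative to the median miRNA. Viral probes (0 detected) were not analysed further.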

Results

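Mature miRNAs were profiled in neural stem and progenitor cells differentiated from mouse ESCs and grown as neurospheres, floating clusters of dividing neural cells. Primary neurospheres were taken at passage 0 (day 6) and secondary neurospheres at passage 1 (day 12). At each passage, NFIA-overexpressing and control cells were sorted apart from the same mixed culture, and each of the 4 resulting samples was hybridised to 1 array. No group had a replicate. The arrays detected 186 to 220 of 611 mouse miRNAs, and the primary array titled control was the dimmest, with a 75th percentile of 167 intensity units over commonly detected probes against 261, 443 and 369 on the primary NFIA OE-titled, secondary control-titled and secondary NFIA OE-titled arrays. Median negative-control signal was 2.92 to 3.72 units. Across the 153 miRNAs detected on all 4 arrays, Pearson's r was 0.927 between the primary arrays and 0.976 between the secondary arrays. Between passages it was 0.780 for the arrays titled control and 0.898 for those titled NFIA OE. These correlations are across miRNAs, which are not independent replicates, and the number of arrays limits the precision of every value.

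The title comparison asked which miRNAs differ with overexpression of NFIA, a transcription factor that promotes the turn of neural progenitors toward making astrocytes. miR-199a-3p and miR-199b*, members of a family best known from mesenchymal cells, were 4.15-fold and 4.0-fold higher on the arrays titled NFIA OE (log2 differences 2.05 and 2.0, SE 0.29, n = 2 arrays per title, limma adjusted p = 1.38e-08 and 1.84e-08). The source names of the samples give the opposite NFIA status in both passages, and by them these and all later title differences would turn their sign. miR-199a-3p differed by 1.74 at passage 0 and 2.37 at passage 1, and miR-199b* by 1.83 and 2.17. With normexp background correction both were smaller, at 1.29 and 0.91, and still called. The 2 arrays per title are 1 from each passage, so the p-values by title measure how far the passages repeat each other. They do not speak for a repeat in other lines or cultures. miR-199a-5p and miR-214 were well above background on both arrays titled NFIA OE and on neither array titled control, at least 3.49-fold and 2.24-fold higher over both passages. By pair these bounds were 1.98-fold and 1.30-fold at passage 0 and 6.15-fold and 3.86-fold at passage 1. As log2 the bounds over both passages were 1.80 and 1.16, and 0.67 and 0.38 with normexp background correction. In the mouse gene table Mir199a-2 lies next to Mir214 and to Dnm3os. Both tested members of the mesenchymal, muscle and endothelial list were thus called higher, also when adjusted over the list alone, while the 10 other members on the array outside miR-199 and miR-214 were not well above background on either array titled NFIA OE.

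On the low side, miR-135b and miR-92b were 2.07-fold lower on the arrays titled NFIA OE (log2 differences -1.05 and -1.05, SE 0.29, limma adjusted p = 0.0195 for both). miR-135b differed by -1.31 and -0.80 in the primary and secondary pairs. miR-92b, read by 5 spots, differed by -1.71 and -0.39, and with normexp it was at -0.43 over both passages and not called. miR-592 was detected only on the arrays titled control, at least 2.30-fold higher there at passage 0 and 1.25-fold at passage 1. In all, limma called 4 of 153 miRNAs by title, 2 higher and 2 lower, and 16 passed an unadjusted p under 0.05 (7 higher and 9 lower). The split was 2 higher and 0 lower with the percentile over all probes, quantile normalization, no scaling or no filter. With detection on at least 1 array it was 5 and 0, of which 2 were among the 4. miR-135b was called in 4 of 10 alternative settings and miR-92b in 3 of 10, while both miR-199 miRNAs were called in 9 of 10. Every title call ended with median centring of the arrays, and also in the fit that left out passage. With median centring the median of the 2 miR-199 differences was 1.95.

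All 9 measured members of the neuronal and neurogenic list were lower on the arrays titled NFIA OE over both passages, with a median difference of -0.39 that lay at percentile 0.03 of level-matched random lists. The median was -0.52 with the authors' processed values and -0.20 without scaling. The member nearest 0 stood at -0.13, so that all were lower depends on the scaling. None of the 9 (0) was called over all miRNAs, and 3 were called lower when adjusted over the list alone. These were miR-124, a neuronal miRNA, at -0.82, miR-153 at -0.80 and miR-7a at -0.76 (SE 0.29 each, limma adjusted p = 0.147 to 0.148 over all miRNAs). miR-153, which has been reported to target Nfia, differed by -0.90 at passage 0 and -0.70 at passage 1. miR-9 and miR-9*, the strands of a precursor abundant in neural progenitors, differed by -0.32 and -0.39, with miR-9* at 0.06 in the primary pair and -0.83 in the secondary pair. The list's median was -0.19 (7 of 9 lower, percentile 8.1) in the primary pair and -0.52 (8 of 9 lower, percentile 0) in the secondary pair.

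Of the other miRNAs reported to target Nfia, miR-322 differed by 0.76 (1.46 at passage 0 and 0.07 at passage 1, limma adjusted p = 0.148, not called) and miR-223 was not well above background on any array (0 of 4). Adjusted over that list alone, miR-322 was called higher and miR-153 lower. The oligodendrocyte-enriched miR-219 differed by -0.74 (adjusted over its list of 1 measured member, lower), with -1.05 at passage 0 and -0.42 at passage 1. miR-338-3p was detected on 3 arrays. All 6 measured astrocyte-enriched miRNAs had higher values on the arrays titled NFIA OE, with none called (0), a median of 0.13 (percentile 81.8) and miR-23b at 0.51. Their sign held only at passage 0, since 5 of 6 were lower at passage 1. The median was near 0 with normexp (0.026), the percentile over all probes (0.024) and the authors' processed values (0.0024). miR-455 (0.74), miR-551b (-0.81), miR-135a (-0.76), miR-210 (-0.74) and miR-130a (-0.34) had the same sign in both pairs and were not called. miR-210 was at -1.14 at passage 0 and -0.33 at passage 1, and the smaller of the 2 miR-455 differences was 0.41.

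The Dlk1-Dio3 imprinted cluster, a maternally expressed group of miRNAs, had 16 of 17 measured members higher on the arrays titled NFIA OE, with a median of 0.29 (percentile 99.96) and 0 called, while the median was 0.077 with normexp, 0.11 with the authors' processed values and -0.19 over all 62 members with no filter. Examples were miR-127 at 0.47, miR-411 at 0.38, miR-329 at 0.35 and miR-300 at 0.29, while miR-495 was at -0.11. The miR-99/100 and miR-125 list had 5 of 5 higher (median 0.43, percentile 99.2, 0 called), led by miR-99a at 0.64, but this came from passage 0, where 5 of 5 were higher (median 0.78), while at passage 1 only 2 of 5 were (median -0.06). Of the miR-17 clusters, which are tied to proliferation, 11 of 12 were lower (median -0.17, percentile 8.6, 0 called, with the median at 0.01 without scaling), from miR-20b at -0.40 to miR-17* at 0.02. At passage 0, 12 of 12 were lower (median -0.27, percentile 1.9), and at passage 1, 8 of 12 were (median -0.15, percentile 60.5). miR-17 stood at -0.32 and miR-106b at -0.11. No member was called (0) of the miR-181 family (median 0.12, or -0.03 with the authors' processed values, and 0.30 and -0.05 at passages 0 and 1, miR-181a at 0.61 and miR-181d at -0.27), the miR-34 and miR-449 list (median -0.33, at -0.76 at passage 0 and 0.10 at passage 1, miR-34c at -0.93 and -0.02), the Sfmbt2 repeats (median -0.00, or 0.19 without scaling, and 0.22 and -0.08 at passages 0 and 1, miR-669f at 0.09 and miR-467f at -0.21) or the miR-15, miR-16, miR-322 and miR-503 list (median -0.23, miR-195 at -0.35). miR-27b at 0.46, miR-24 at 0.25 and miR-21 at -0.13 were not called either.

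**Figure D1:**
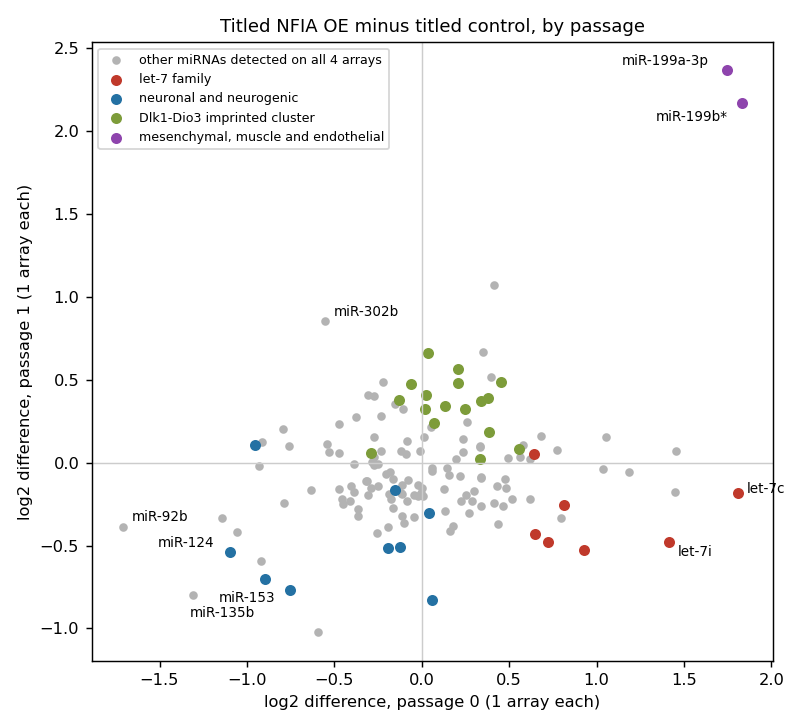
Log2 difference, array titled NFIA OE minus array titled control, at passage 0 (x axis) and passage 1 (y axis) for the 153 miRNAs detected on all 4 arrays, 1 point per miRNA, coloured by list. miR-199a-3p (1.74, 2.37) and miR-199b* (1.83, 2.17) stand apart, and let-7c lies at 1.81 and -0.18.

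Title differences in the primary and secondary pairs were weakly correlated, mostly through miR-199. Pearson's r across the 153 miRNAs was 0.328 (95% interval 0.179 to 0.463, Spearman's rho 0.145). It was 0.144 without miR-199a-3p and miR-199b* (95% interval -0.0163 to 0.297, which includes 0). Both intervals take miRNAs as independent, which related miRNAs are not, so they may be too narrow. With normexp background correction r across the 153 was 0.105. The let-7 family, whose mature forms increase as stem cells differentiate, showed this most plainly. All 7 measured members were higher on the primary array titled NFIA OE (median 0.81, percentile 99.8), and 6 of 7 were lower on the secondary one (median -0.43, percentile 0.835). let-7c differed by 1.81 and -0.18, let-7i by 1.41 and -0.48 and let-7a by 0.81 and -0.25. Over both passages the family's median was 0.28 (percentile 99.0), with 0 of 7 called and let-7c alone called when adjusted over the list. miR-99a followed let-7c, with 1.45 and -0.18, and the gene table lists Mir99a beside Mirlet7c-1 and Mir125b-2. miR-302b (-0.55, 0.85), miR-92b and miR-218 (-0.95, 0.11) moved most the other way. The 0.85 of miR-302b rests on a level at the lowest detected signal of the secondary array titled control. The interaction itself had no test, because the additive fit takes it as residual. Counting single pairs, 16 of 179 miRNAs were at least 2-fold apart by title at passage 0 (9 higher and 7 lower) and 9 of 195 at passage 1 (7 higher and 2 lower). At passage 0 the split was 36 higher and 1 lower without scaling, 6 and 16 with median centring, 8 and 13 with the authors' processed values and 1 and 1 with normexp, and at passage 1 it was 5 and 5 without scaling.

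The passage comparison asked how miRNAs differ between secondary and primary neurospheres. Passage and days in culture go together in these samples, so the 2 cannot be told apart. let-7c rose 6.56-fold from passage 0 to passage 1, miR-9* 6.06-fold, miR-210, a hypoxia-induced miRNA, 5.81-fold, and miR-9 3.65-fold (log2 differences 2.71, 2.60, 2.54 and 1.87, SE 0.29, n = 2 arrays per passage, limma adjusted p from 1.88e-14 to 3.82e-08). miR-302b, a miRNA of pluripotent cells, was 9.42-fold lower at passage 1 (-3.24, limma adjusted p = 7.65e-19). It was read by 1 probe and 5 spots. On the secondary array titled control its level of -4.34 was the lowest of any detected probe. Over 10 alternatives the differences ran from 2.10 to 3.67 for let-7c, 2.20 to 3.55 for miR-9*, 1.82 to 3.49 for miR-210, 1.71 to 2.82 for miR-9 and -3.37 to -1.90 for miR-302b, each with its smallest size under normexp background correction. Many miRNAs of the Dlk1-Dio3 cluster fell, among them miR-541 (-1.99), miR-410 (-1.93), miR-495 (-1.83) and miR-300 (-1.76). limma called 70 of 153 miRNAs, 20 higher and 50 lower, and 78 passed an unadjusted p under 0.05.

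All passage differences shift together with the scaling between arrays, and the median miRNA stood at -0.39. Taken relative to that median, 53 miRNAs were called, 26 higher and 27 lower, 47 of them among the 70. The split was 39 higher and 17 lower with the authors' processed values, 25 and 5 with the percentile over all probes, 21 and 30 with quantile normalization, 20 and 1 without scaling and 14 and 73 with normexp background correction. Median centring of the arrays left 0 called by limma, with 44 at an unadjusted p under 0.05. The directions given here for let-7, miR-9, miR-9*, miR-210, miR-99a, miR-302b and the Dlk1-Dio3 miRNAs named were the same under each of these.

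All 7 measured members of the let-7 family were higher at passage 1 (family median 1.74, percentile 99.6). limma called 6 of them, or 7 relative to the median miRNA. let-7d (2.39), let-7i (2.11), let-7f (1.74), let-7g (1.52) and let-7a (1.51) rose, with higher values at passage 1 in both pairs, and let-7b was detected on every array except the primary one titled control. The family median was 2.28 in the pair titled control and 1.17 in the pair titled NFIA OE, with let-7i at 3.06 and 1.17 and let-7a at 2.04 and 0.97. miR-99a (1.89) and miR-125b-5p (0.71, adjusted p = 0.0388) rose with miR-100 (0.97), which made 3 of 5 called in the miR-99/100 and miR-125 list (median 0.71, percentile 95). Called were 2 of 5 with detection on at least 1 array, 1 of 5 with quantile normalization and 0 with median centring. miR-125b-5p was called in 6 of 10 alternatives, and with quantile normalization it was at 0.53 (adjusted p = 0.113). Their differences were larger in the pair titled control than in the pair titled NFIA OE, at 2.70 and 1.08 for miR-99a, 1.13 and 0.29 for miR-125b-5p and 1.59 and 0.34 for miR-100. In the neuronal and neurogenic list miR-9 and miR-9* rose, miR-124 (-1.28) and miR-7a (-1.12) were called lower, and the other 5 were not called (list median -0.26, percentile 59.7, but above 0 under 5 other scalings, at 0.40 with the authors' processed values). Neither lower call held with the authors' processed values, the percentile over all probes or no scaling, where miR-124 was at -0.65, -0.53 and -0.33. miR-153 was at -0.65 (adjusted p = 0.0612). miR-21 rose by 1.02 (1.30 in the pair titled control and 0.73 in the pair titled NFIA OE). miR-322 was called higher at 1.0, with most of the difference in the pair titled control (1.69 against 0.31). miR-23a, at 0.78, was the member called of 6 astrocyte-enriched miRNAs (median 0.20, percentile 95, but -0.16 with normexp background correction and -0.08 in the pair titled NFIA OE), though adjusted over that list alone 0 were called.

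All 17 measured Dlk1-Dio3 miRNAs were lower at passage 1, of which limma called 16, or 15 relative to the median miRNA (list median -1.46, percentile 0). Among those called were miR-376c (-1.56), miR-329 (-1.48), miR-379 (-1.46) and miR-127 (-1.42). Without scaling 0 of the 17 were called and with the authors' processed values 13, all with a negative list median. The cluster's detected members went from 27 and 35 on the primary arrays titled control and NFIA OE to 18 and 17 on the secondary ones. miR-335-5p fell by 1.63 on the log2 scale. All 12 measured members of the miR-17 clusters fell (median -0.99, percentile 0.07), with miR-92a at -1.46, miR-17 at -1.18 and miR-106b at -0.85. Relative to the median 5 of the 12 were called, and 2 with the authors' processed values (list median -0.35). None (0) was called without scaling (list median -0.04), with the percentile over all probes (-0.24) or with median centring (-0.51). Without scaling miR-106b turned to 0.10, so that all 12 fell depends on the scaling. miR-34a, miR-34b-5p and miR-34c fell (median -1.18, miR-34c at -1.24), of which 2 were called relative to the median and 0 with the authors' processed values, the percentile over all probes, no scaling or median centring (list medians -0.54, -0.43, -0.23 and -0.70). Their median was -1.61 in the pair titled control and -0.75 in the pair titled NFIA OE, with miR-34c at -1.70 and -0.79.

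Pluripotency miRNAs were concentrated at passage 0. miR-293 of the miR-290 cluster was at least 9.04-fold higher there and miR-302a at least 4.18-fold, both undetected on the secondary arrays (log2 bounds of 3.18 and 2.07, but 1.73 and 1.19 with normexp background correction and 2.23 and 1.11 without scaling). Detected members of the miR-290 cluster numbered 5 and 6 on the primary arrays titled control and NFIA OE and 0 and 4 on the secondary ones, and those of the miR-302 cluster 5, 5, 1 and 3. miR-363 (at least 7.75-fold in the pair titled control and 2.64-fold in the pair titled NFIA OE) and miR-431 (at least 3.66-fold over both) were also detected only at passage 0 (log2 bounds over both pairs of 2.18 and 1.87, but 1.23 and 1.12 with normexp and 1.23 and 0.92 without scaling). In the other direction, miR-10b of the Hox clusters was detected only at passage 1, at least 2.70-fold higher there in the pair titled control and 18.9-fold in the pair titled NFIA OE. Its log2 bound over both pairs was 2.84, but smaller with normexp background correction and larger without scaling. In all, 17 miRNAs were detected only on both primary arrays and 13 only on both secondary arrays. Log2 bounds ran from 0.94 to 3.18 for the 17, but from -0.74 to 2.84 for the 13, with most of the 13 below 0. The lowest detected signal was higher on the primary arrays (-3.24 and -3.97) than on the secondary ones (-4.34 and -4.27). Detection at passage 1 alone thus need not mean a higher level there.

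Among the remaining lists, 3 of 4 miR-181 members had higher values at passage 1 and limma called 1 of them (miR-181a at 0.79, miR-181d at -0.43, median 0.13, percentile 95.4, but -0.24 with normexp background correction). Of the miR-15, miR-16, miR-322 and miR-503 list 2 of 5 had higher values and 1 was called (miR-322, with miR-15b at -0.34, median -0.17, but 0.48 with the authors' processed values). With normexp miR-181a was no longer called (0.28, limma adjusted p = 0.276), and miR-181d was called lower (-0.55, limma adjusted p = 0.0336). In the pairs titled control and NFIA OE the miR-181 median was 0.31 and -0.04, with miR-181a at 1.24 and 0.35. The Sfmbt2 repeats had 0 of 7 called (median -0.22, but 0.42 with the authors' processed values, miR-466f-3p at -0.63, miR-467a* at 0.10), and neither miR-199a-3p (-0.29), miR-199b* nor miR-219 (-0.44) was called. Epithelial miRNAs were detected on no array (0 of 12 members). Of blood cell markers only miR-155 was detected, on both primary arrays, of endodermal markers only miR-375, on the primary array titled control, and of the miR-183 cluster 1 and 2 members, on the primary arrays only.

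**Figure D2:**
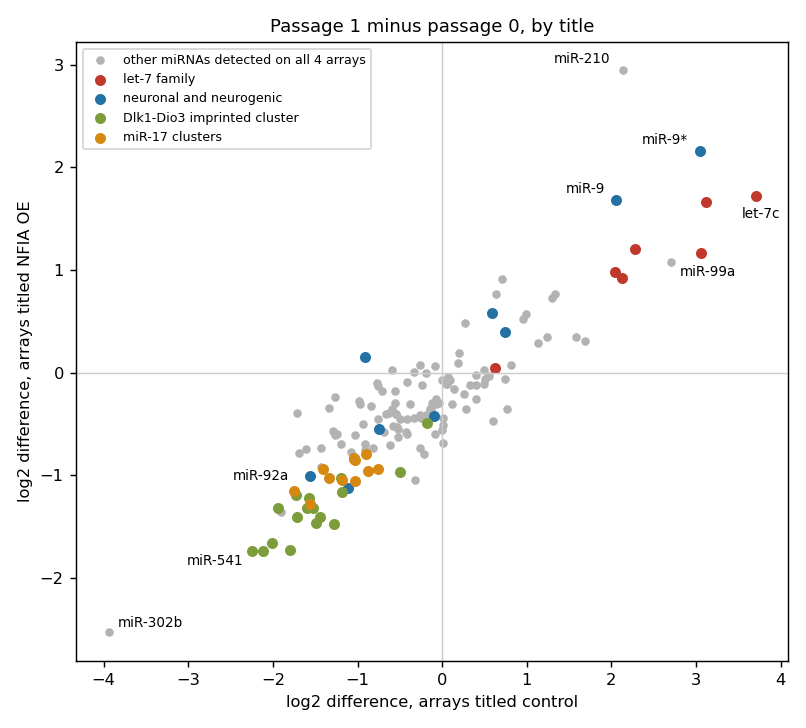
Log2 difference, passage 1 minus passage 0, for arrays titled control (x axis) and titled NFIA OE (y axis), 1 point per miRNA detected on all 4 arrays (153), coloured by list. let-7 (red) and miR-9/miR-9* lie at the upper right, Dlk1-Dio3 miRNAs (green), miR-17 clusters (orange) and miR-302b at the lower left, with Pearson's r of 0.893.

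Both titles gave closely similar passage differences. Pearson's r across the 153 miRNAs was 0.893 (95% interval 0.856 to 0.921, which takes related miRNAs as independent). The pairs have no array in common, but at each passage both arrays came from the same mixed culture, so neither this r nor the p-values by passage speak for a repeat of the passages in other cultures. Among single pairs, 58 of 160 miRNAs were at least 2-fold apart between the arrays titled control (16 higher and 42 lower) and 42 of 188 between those titled NFIA OE (10 higher and 32 lower). These splits followed the scaling, at 35 higher and 13 lower and 29 and 10 with the authors' processed values, 79 and 1 and 23 and 11 without scaling, and 27 and 23 and 18 and 15 relative to the median miRNA of each pair. The SD of the passage difference over the 153 miRNAs was 1.16 in the pair titled control and 0.76 in the pair titled NFIA OE. let-7c differed by 3.71 in the former and 1.72 in the latter, and miR-302b stood at -3.94 and -2.53. The -3.94 rests on a miR-302b level at the lowest detected signal of the secondary array titled control.

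**Figure D3:**
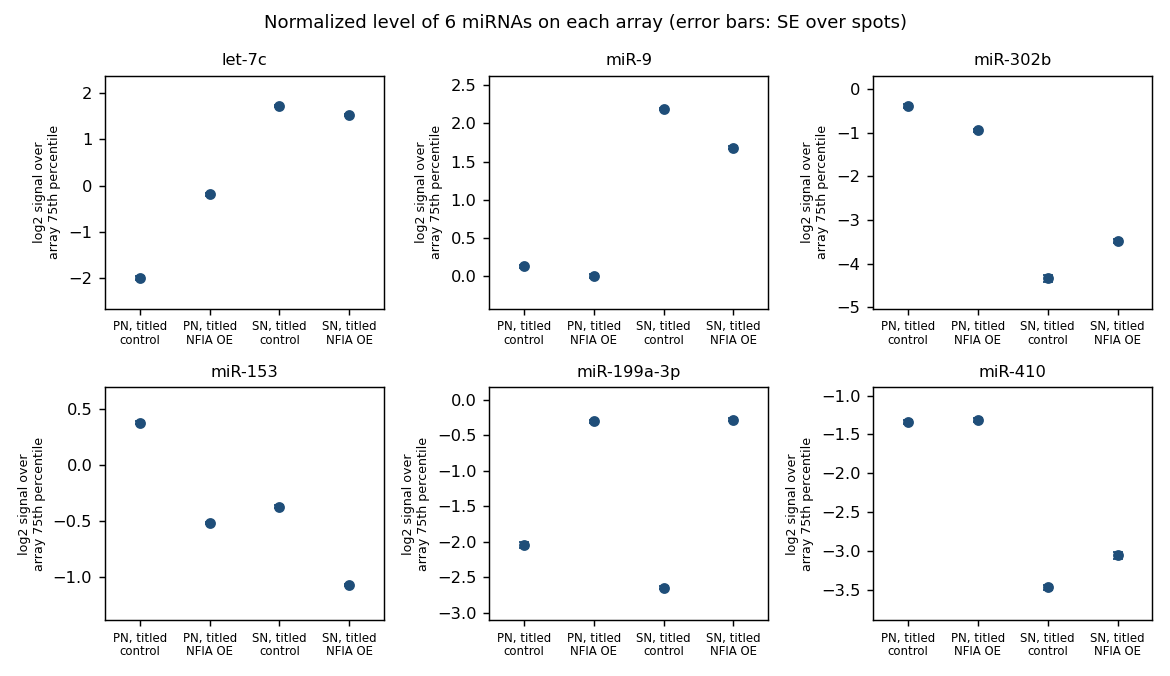
Normalized log2 level of 6 miRNAs on each of the 4 arrays, as signal over the array's 75th percentile, with the SE over spots as error bars (smaller than most points). let-7c goes from -2.0 on the primary array titled control to 1.71 on the secondary one, and miR-199a-3p lies at -2.05 and -2.65 on the arrays titled control against -0.31 and -0.28 on those titled NFIA OE.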

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

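The 2 tests in the paragraph after this one were written down before they were run, and the pattern they address was chosen after the results were seen. The miRNAs here have title differences of opposite sign in the primary and secondary pair, each with a 95% interval from its SE over spots that excludes 0. That error is technical only, each pair is 1 array against 1, and the difference between pairs was not tested. Among 42 named and measured miRNAs 10 met this by title, and 1 of 39 by passage. The naming rule partly fixes these counts. In each set the 10 highest and 10 lowest were named for the same sign in both pairs, so they could not be flagged. The title set alone also held miRNAs named because their title difference changed most between passages. Of those flagged by title, let-7i and miR-218 entered only this way. The counts by title and by passage therefore cannot be compared. Going from the primary to the secondary pair, the title difference changed by -1.99 for let-7c (1.81 to -0.18), -1.89 for let-7i (1.41 to -0.48), -1.63 for miR-99a (1.45 to -0.18) and -1.07 for let-7a (0.81 to -0.25). Smaller falls were -0.84 for miR-125b-5p (0.62 to -0.22), -0.66 for miR-669f (0.42 to -0.24) and -0.57 for miR-21 (0.16 to -0.41). The change ran the other way for miR-302b, by 1.41 (-0.55 to 0.85), miR-218, by 1.06 (-0.95 to 0.11), and miR-34a, by 0.70 (-0.22 to 0.48). On the secondary array titled control the miR-302b level was the lowest of any detected probe. By passage, miR-467a* went from 0.33 in the arrays titled control to -0.12 in those titled NFIA OE, a change of -0.45.

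These changes fall along the passage difference: at passage 0 the array titled NFIA OE leaned toward the passage 1 profile (r = 0.264 across 153 miRNAs between its title difference and the passage difference of the arrays titled NFIA OE, although the array these differences share pushes that r down), and at passage 1 its partner leaned away (r = -0.302, although there the shared array pushes r up). A trend with signal level is argued against, since after removing a loess fit on level r stayed at 0.254 (95% interval 0.0990 to 0.396) and -0.240. The intervals here take miRNAs as independent, which related miRNAs are not, so they may be too narrow. For signal shared among let-7 probes, the passage 0 value without let-7 was 0.117, with an interval that includes 0, and the passage 1 value was -0.257. Leaving out let-7, which changed most, lowers the passage 0 value whether or not its probes share signal. The test therefore cannot decide, and this explanation stays open. A difference between the sorted cell populations in how far they had matured at each passage may also be the source and was not tested.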

How the results depend on the processing

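The settings compared here were fixed before the data were examined, except the robust prior, the correlations without miR-199 and the differences relative to the median miRNA, which were chosen after seeing the data. Unless stated, the cause of a change was not tested.

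By title limma called 4 miRNAs, and 2 with the percentile over all probes, 2 with quantile normalization, 2 without scaling and 2 without a filter on dim probes. Without passage in the fit limma called 0 (2 at an unadjusted p under 0.05), where by construction the passage difference enters the residual. Centring each array on its median also left 0 by title (6 at an unadjusted p under 0.05). By passage limma called 70, against 30 with the percentile over all probes, 21 without scaling and 0 after median centring (44 at an unadjusted p under 0.05). After median centring the residual SD was 0.29, as before, while the estimated prior had 3.14 degrees of freedom in place of infinite, and miR-199a-3p had an adjusted p of 0.392. Over 10 alternatives its title difference ran from 1.29 to 2.24.

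Title differences of at least 2-fold numbered 16 at passage 0, but 2 with normexp background correction and 37 without scaling, and 9 at passage 1, but 4 with normexp. Passage differences of at least 2-fold went from 58 in the arrays titled control to 90 with detection on at least 1 array and 476 with no filter, which add miRNAs near background by construction. In the arrays titled NFIA OE they went from 42 to 18 with normexp and 64 with detection on at least 1 array. The correlation of the title differences was 0.328, and 0.144 without miR-199, 0.105 with normexp and 0.0837 with no filter. For the passage differences it was 0.893, and 0.807 with detection on at least 1 array and 0.742 with no filter.

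These title differences turned their sign, each close to 0 and none called. miR-17* became -0.00405 with normexp, -0.086 with the percentile over all probes, -0.10 with quantile normalization, -0.049 with median centring, -0.046 with total gene signal and -0.11 with the authors' processed values. miR-302b became -0.035 with normexp, -0.098 with quantile normalization and -0.012 with the authors' processed values. miR-669f became -0.060 with normexp, -0.023 with the percentile over all probes and -0.030 with the authors' processed values. miR-21 became 0.015 with quantile normalization and 0.061 without scaling. Without scaling miR-106b was at 0.0751 and miR-495 at 0.0746, and with the authors' processed values miR-34a was at -0.00222. The Dlk1-Dio3 median by title became -0.19 with no filter, over 62 members.

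Among passage differences, miR-467a* became -0.33 with normexp. The other changes of sign came with scaling, which by construction adds 1 constant to every miRNA, except for quantile normalization, and for the authors' processed values, where probes are also summarised differently. With the percentile over all probes miR-153 was at 0.10, miR-219 at 0.31, miR-23b at 0.50, miR-199a-3p at 0.46, miR-99b at 0.41, miR-181d at 0.32, miR-466f-3p at 0.12 and miR-15b at 0.41. Quantile normalization put miR-23b at 0.0096, miR-199a-3p at 0.021, miR-99b at 0.079, miR-181d at 0.035 and miR-466f-3p at 0.064. No scaling gave miR-153 at 0.30, miR-106b at 0.10, miR-219 at 0.51, miR-23b at 0.70, miR-199a-3p at 0.66, miR-99b at 0.62, miR-181d at 0.52, miR-466f-3p at 0.32 and miR-15b at 0.61. After median centring miR-219 was at 0.035, miR-23b at 0.23, miR-199a-3p at 0.19, miR-99b at 0.14, miR-181d at 0.050 and miR-15b at 0.14. The authors' processed values gave miR-153 at 0.019, miR-219 at 0.19, miR-23b at 0.39, miR-199a-3p at 0.36, miR-99b at 0.30, miR-181d at 0.19, miR-466f-3p at 0.12 and miR-15b at 0.30.

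Lower bounds for one-sided miRNAs fell with normexp, from 1.80 to 0.67 for miR-199a-5p, 1.16 to 0.38 for miR-214, 0.93 to 0.34 for miR-592, 3.18 to 1.73 for miR-293, 2.84 to 1.20 for miR-10b, 2.18 to 1.23 for miR-363, 2.07 to 1.19 for miR-302a and 1.87 to 1.12 for miR-431. Without scaling the bounds were 2.23 for miR-293, 3.79 for miR-10b, 1.23 for miR-363, 1.11 for miR-302a and 0.92 for miR-431.

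Leaving out each array leaves 1 intact pair and no test. The miR-199a-3p title difference then ranged from 1.74 to 2.37, that of miR-92b from -1.71 to -0.39, and that of miR-322 from 0.07 to 1.46. The passage difference of let-7c ranged from 1.72 to 3.71, that of miR-322 from 0.31 to 1.69 and that of miR-125b-5p from 0.29 to 1.13.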

Other observations

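The secondary array titled NFIA OE carried miRNAs encoded in the Hox clusters that its partner had at lower levels or not above background. miR-10a was 15.2-fold higher there than on the secondary array titled control (log2 difference 3.92) and miR-10b 4.22-fold (2.08). The 15.2-fold divides by a dim value. On the secondary array titled control miR-10a lay below the lowest detected signal of the primary array titled control, after scaling (log2 bound -0.72). miR-196a was at least 4.48-fold higher and miR-196b at least 2.59-fold, both detected on that array alone. Neither primary array had a detected Hox cluster miRNA (0 and 0 of 9 members). In the mouse gene table Mir10a lies next to Hoxb4, Mir10b next to Hoxd4, Mir196a-1 next to Hoxb9 and Mir196b next to Hoxa10. The same array kept more of the pluripotency miRNAs, with miR-291a-3p, miR-292-3p, miR-294 and miR-295 detected there (4 members) and 0 members of the miR-290 cluster on its partner. miR-294 and miR-295 were nonetheless 3.5 and 3.55 log2 units below the primary array titled NFIA OE. These values come from single arrays without a test and were chosen after they were seen.

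Tests of the miR-199 pattern were chosen after the result was seen. miR-199a-3p, miR-199b*, miR-199a-5p and miR-214 were higher on the array titled NFIA OE at both passages. Scaling between arrays is argued against, because the lowest miR-199a-3p difference over 5 scaling alternatives was 1.92. Probes reading near-identical copies of 1 miRNA could raise together only those miR-199 values that come from the same strand, and for these they stay open. miR-214 is unlike miR-199 in sequence, but its bound of 1.16 log2 units belongs to the pattern itself and so decides nothing. Muscle, endothelial or other mesenchymal cells among the sorted cells stay open: 0 of 10 other markers on that list were well above background, but dim markers could lie below it. A difference between the sorted lines, including NFIA itself, may be the source and was not tested, and the conflicting labels leave unknown which line it would be.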
